A study of Homo sapiens with 22 samples.

How the data were processed

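U937 cells were fixed with formaldehyde, sonicated and immunoprecipitated with antibodies bound to protein A beads, per the labels' protocols, and 1 library per antibody was analysed. Groups were taken from the labels. H3ΔN and bulk H3 have 3 U937 libraries each in the labels, of which 1 each was used here, and CTSG, PRTN3 and ELANE have 1 each. The 3 come from separate sets, each with its own replicate 1. Among these U937 libraries only the titles of the set with the input DNA name ChIP-seq. The input DNA library, the other U937 libraries and those of monocytes and macrophages (3 for each cell type and antibody) were not analysed here.

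FastQC, Bowtie2, Picard and MACS2 are named with the build GRCh38 in the submitters' processing notes, without versions or roles. The files are peak lists in the 10-column form that MACS2 writes and have no header. The control library, the q threshold, the treatment of duplicates and reads with several matches, and any filter of problem regions are not given in the sources used here. Peaks were called per library as far as the files show, since each list belongs to 1 sample. The peak names in the 5 lists carry 1 common pool and lane tag. Per the layout of the deposited lists, column 7 is the fold (a linear ratio of signal at the summit to its background), columns 8 and 9 are −log10 p-values and −log10 q-values, and column 5 is a deposited score that follows column 9. The score was not used in any result. Because background and depth enter the fold, and depth is unknown, folds were not compared between lists. A library with more reads or a better antibody gives more peaks at the same q, so list lengths do not measure the amount of protein.

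Coordinates were converted to 1-based positions. Entries with the same interval are summits of 1 region. Positions relative to genes used summits, and overlaps, gene hits and densities used regions. Genes came from a RefSeq table for GRCh38.p14 with 59080 genes placed on chromosomes 1 to 22 and X, of which 19970 are protein-coding. The table has gene spans and no strand, exons or sequence. The planned promoter (1 kb around a transcription start) was therefore replaced by 1 kb around either end of the span, and classes for exons, introns and untranslated regions were replaced by gene end, elsewhere inside a protein-coding gene, inside another gene and outside. Base composition of peaks was not analysed here. Random placements put each peak at a random site of its chromosome 1000 times. In place of assembly gaps, bins of 1 Mb without any annotated gene were left out (160 Mb in total), which left 2882 Mb. A value was called different when it lay outside all 1000 placements. Overlap meant at least 1 bp.

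For each of 25 gene lists, fixed before the data were examined, the number of members with a region at an end was ranked among 10000 random lists of as many protein-coding genes with the same spread over 20 bins of gene span. A list stood apart when it lay in the outermost 0.1% on either side. These are descriptions of 1 library, not p-values, and genes that share a region (such as divergent pairs) each count. The lists were cell cycle, chromatin regulators, cytosolic ribosomal proteins, mitochondrial respiratory chain, proteasome subunits, replication-dependent histone genes, spliceosome, lysosome, azurophil granule proteins, monocyte markers, macrophage markers, myeloid transcription factors, Toll-like receptor and NF-kB signalling, interferon-stimulated genes, inflammatory cytokines and chemokines, MHC class II presentation, HOX genes, ZNF zinc finger genes, T cell markers, B cell markers, erythroid markers, hepatocyte genes, neuronal genes, keratins and keratin-associated proteins, and olfactory receptors.

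Genes and regions to name were set by rule before the data were examined. The rule took the 10 protein-coding genes with the strongest H3ΔN peak at an end, from each list the 3 members with the strongest such peak and the first 2 in alphabetical order without one, the genes CTSG, PRTN3, ELANE, SPI1, CD14, CSF1R and MYC, the 5 strongest peaks of each other list with the nearest protein-coding gene, and the 5 H3ΔN peaks under the strongest protease peaks. The text gives a selection of these. Some genes that the rule takes are not reported here. Histone genes beyond the 3 strongest, the 7 other genes with PRTN3, the PLPPR3 region and everything named for snRNA genes, wide domains and chromosomes were chosen after their values were seen.

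Shares carry 95% Wilson intervals, and a count of 0 is given with the limit of 3 counts of the total. The placements and list ranks were tested on simulated data over the 19970 genes: a planted excess of 20% of H3ΔN summits at gene ends was recovered as 19.8%, a planted overlap of 30% of regions as 29.0%, and none of 200 random lists but 200 of 200 lists of 25 genes with 90% marked genes stood apart. Alternatives tried were stricter −log10 q thresholds of 5 and 10, windows of 500 bp and 2.5 kb, whole regions, a larger overlap, placements within position classes or over whole chromosomes, ranking by q or width, and unmatched lists. Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.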

Results

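The series profiled where a cleaved form of histone H3 lies on the genome of human monocytic cells. The form, written H3ΔN here, lacks the N-terminal tail up to a cut near Thr22. ChIP-seq was run with antibodies to H3ΔN, to bulk H3 and to CTSG (cathepsin G), PRTN3 (proteinase 3) and ELANE (neutrophil elastase), serine proteases that neutrophils and monocytes store in azurophil granules. The labels list 22 samples, of which 5 were analysed: the peak lists of 1 library per antibody, all from U937, a monocytic cell line. The other 17 samples were not analysed here. They are an input DNA library of U937, further U937 libraries for H3ΔN and bulk H3, and the same antibodies in monocytes and monocyte-derived macrophages. The read depth of the 5 libraries is unknown, and with 1 library per antibody no value below has a replicate error. Intervals are 95% Wilson intervals of a share and cover counting error only. A fold is the enrichment that the authors deposited for a peak, and it is used only to rank and describe peaks within a list, so folds of different lists at the same place are not comparable. All positions are on GRCh38.

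The first comparison asked how many peak regions each antibody gave. H3ΔN gave 46325 peak entries in 31286 separate regions that covered 16.9 Mb, with a median width of 398 bp and a median fold of 3.05. The PRTN3 list held 57 regions with a median fold of 4.46, and the CTSG list held 229 with a median fold of 3.34. The ELANE list held 14 regions and the bulk H3 list 19, and these covered 10.8 kb and 11.7 kb. A peak is a local excess over background, so evenly spread signal gives few peaks. These lengths therefore do not measure how much of the genome bulk H3 or a protease occupies. The lists also differed in how many regions passed a q-value of 0.05: 81.5% for H3ΔN, 84.2% for PRTN3, 68.4% for bulk H3, 57.1% for ELANE and 26.6% for CTSG, that is 61 of 229 CTSG regions. The lowest deposited −log10 q was between 0.602 and 0.654 in every list, so all 5 went down to a q just under 0.25. At a −log10 q of at least 5, 11402 regions remained for H3ΔN, 31 for PRTN3, 8 for bulk H3, 7 for ELANE and 5 for CTSG. No test between antibodies was possible with 1 library each.

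The next comparison asked where H3ΔN peaks lie relative to genes. H3ΔN peaks were concentrated at the ends of protein-coding genes. On the chromosomes 1 to 22 and X, 16166 of 46313 summits (34.9%, interval 34.5 to 35.3%) lay within 1 kb of either end of such a gene. In 1000 random placements on the same chromosomes the mean was 2.92% and the highest 3.19%, so the observed share was 11.95 times the mean. Summits elsewhere inside protein-coding genes made up 39.0% against a mean of 43.7% in the placements, and summits inside other annotated genes 9.002% against 13.9%. Only 17.1% lay outside annotated genes against 39.5%, and all 4 shares fell outside the range of the 1000 placements. With a window of 500 bp the share inside protein-coding genes was above the placements instead, at 47.3% against 44.5%. The annotation used gives no strand, so transcription starts and ends were not told apart. Bulk H3 had 0 of 14 summits at a gene end (upper Wilson bound 21.5%), and 748 of 1000 placements had none either. That list is too short to serve as a baseline, and the control library is unknown. Signal that any antibody would give at gene ends, here or in the gene lists below, was therefore not told apart from H3ΔN.

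**Figure D1:**
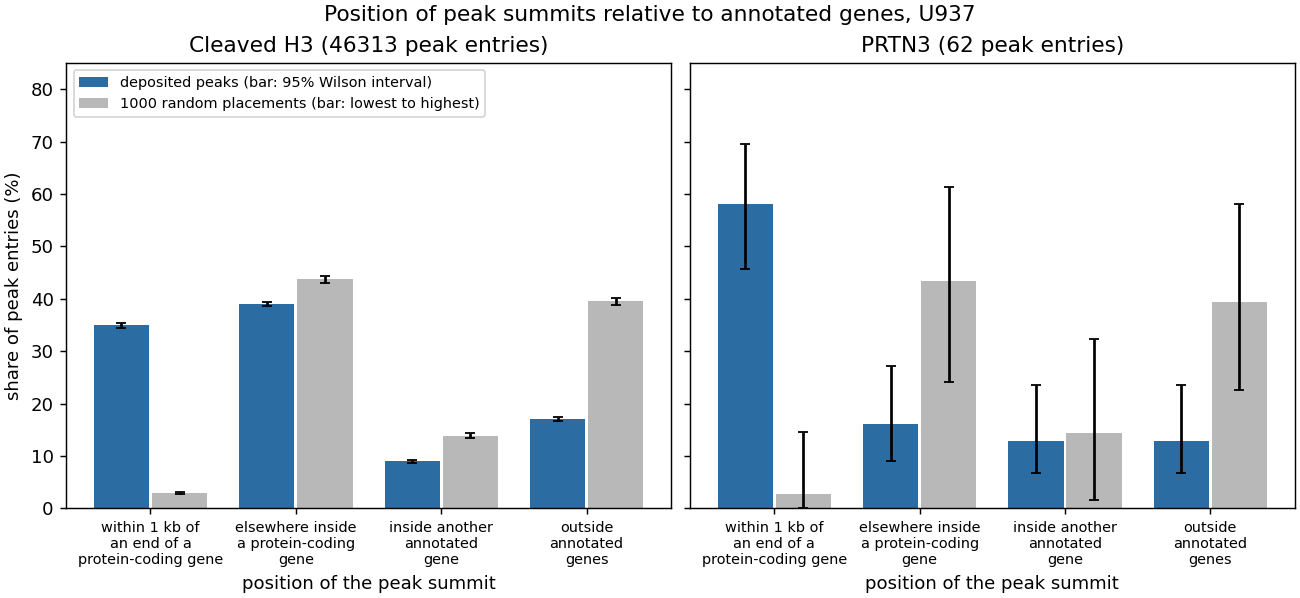
Share of peak summits (%, vertical axis) by position relative to annotated genes (horizontal axis) for H3ΔN (left, 46313 entries) and PRTN3 (right, 62 entries). Blue bars are the deposited peaks with 95% Wilson intervals, and grey bars are the mean of 1000 random placements with their lowest and highest values. Gene ends hold 34.9% of H3ΔN and 58.1% of PRTN3 summits, against 2.92% and 2.80% in the placements.

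The 10 genes with the strongest H3ΔN peaks at an end had folds from 9.38 to 10.0. The highest fold on a gene end was 10.0, at ANP32E (gene 81611), a chaperone that removes the histone variant H2A.Z, in a region at chromosome 1, 150234354 to 150236010. A region at chromosome 3, 52410583 to 52412081 with a fold of 9.75 covered an end of PHF7 and lay within 1 kb of BAP1 (gene 8314), a deubiquitinase of histone H2A. KBTBD11 followed at 9.70 with a region of 5256 bp, then RHEB, an activator of mTORC1, at 9.61 and HOMER3 at 9.55. FUT4, the enzyme that makes the myeloid surface sugar CD15, stood at 9.52 and HHEX, a homeobox regulator of blood cells, at 9.46. A region at chromosome 7, 26201726 to 26202955 with a fold of 9.38 was shared by CBX3, which encodes the heterochromatin protein HP1γ, and HNRNPA2B1, an RNA-binding protein. None of these 10 genes had a PRTN3, CTSG, ELANE or bulk H3 region at an end, but such regions were rare at any gene. Of all 19970 protein-coding genes 32 had one of PRTN3, 1 of ELANE and 0 of CTSG or bulk H3. A count of 0 among 10 genes therefore says nothing about these genes.

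Peak strength and position went together within the H3ΔN list. Among summits in the lowest quartile of fold (1.39 to 2.57), 26.4% lay at a gene end (interval 25.6 to 27.2%), and in the next quartile 26.5%. The share was 34.5% in the third quartile and 52.3% (51.4 to 53.2%) in the highest, which ran from 3.68 to 10.0. The share outside annotated genes went the other way, from 20.8% in the lowest to 10.1% in the highest quartile. Summits at gene ends had a median fold of 3.31, against 2.93 inside protein-coding genes and 2.83 outside annotated genes.

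The next comparison asked which kinds of gene carried H3ΔN at an end. Of 19970 protein-coding genes 9134 did (45.7%), and 25 gene lists were set against 10000 random lists each, matched on gene span. The lists with more marked genes than random lists held genes of basic cell machinery. All 26 spliceosome genes were marked, among them SRSF2 at a fold of 6.79 and SNRPD3 at 6.27. Of the cytosolic ribosomal protein genes 82 of 83 were marked, led by RPS15 at 7.17 and RPL10A at 6.76. The cell cycle list reached 31 of 32, with MKI67, the proliferation marker, at 7.80, CDK1 at 6.91 and TOP2A at 6.60, and CENPE without a peak at an end. Of the chromatin regulators 25 of 26 were marked, including the histone methyltransferases DOT1L at 8.21 and EZH2 at 7.46, and NSD1 was not. Mitochondrial respiratory chain genes reached 70 of 87 (UQCRFS1 8.49, COX5A 6.56), proteasome subunits 31 of 39 (PSMA7 5.96, PSMD8 5.69) and replication-dependent histone genes 47 of 69 (H1-4 8.45, H4C11 6.68). The percentile was 99.995 for the proteasome list, where 1 random list of 10000 reached the count, and 100 for the other 6.

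Lists with fewer marked genes than random lists numbered 5, all of genes typical of other cell types. Only 4 of 390 olfactory receptor genes (OR51Q1 3.53, OR52W1 3.29) and 2 of 149 keratin and keratin-associated genes (KRT10 4.40, KRTAP16-1 3.34) had an H3ΔN peak at an end, both at a percentile of 0. T cell markers had 2 of 22, namely CD4 at 3.14, which monocytes also express, and LAT at 2.70, while CCR7 and CD247 had none. Hepatocyte genes had 2 of 23 (TF 3.84, CPS1 3.14), with ALB and AHSG unmarked, and neuronal genes had 2 of 23 (DLG4 4.44, GRIN1 2.42). These 3 lists each stood at a percentile of 0.015. With H3ΔN peaks at a −log10 q of at least 10, 2 lists remained below random lists. T cell markers then had 0 of 22 marked (percentile 0.185), hepatocyte genes 0 of 23 (0.29) and neuronal genes 1 of 23 (2.33). A count of 0 is the lowest possible, so the T cell and hepatocyte lists could not pass the limit in this setting. Their percentiles therefore do not show that the shortage of marked genes was lost. Hepatocyte genes also came inside the limits with a window of 2.5 kb (5 of 23, percentile 0.5), and neuronal genes with any peak over the gene counted (9 of 23, percentile 1.18). At that threshold the spliceosome list (99.8) and the proteasome list (88.5) also lay inside the limits.

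The other 13 lists did not reach the outermost 0.1% on either side. Of 26 myeloid transcription factors 17 were marked (percentile 99.4), with GFI1 at 8.62 in the longest region of the list (8860 bp), MYB at 8.48 and CEBPA, a driver of granulocyte and monocyte fate, at 8.13. CEBPD and EGR1 were unmarked, and the percentile was 100 at a −log10 q of at least 10 and 99.975 with a window of 2.5 kb, but 97.7 against unmatched random lists. Azurophil granule genes had 9 of 15 (AZU1 6.91, RNASE3 5.90, SERPINB1 5.72), Toll-like receptor and NF-kB genes 18 of 25 (NFKB1 6.33, NFKBIA 5.87) and lysosome genes 17 of 24 (CTSD 6.32, CTSZ 6.12), at percentiles of 94.4, 98.5 and 98.2. Monocyte markers had 12 of 22 (CLEC12A 5.82, CSTA 4.98) at 71.7, but 0 of 22 at 0.335 with peaks at a −log10 q of at least 10 and 17 of 22 at 98.3 with any peak over the gene. Inflammatory cytokines and chemokines had 6 of 22 (CXCL2 4.73, TNF 3.45) at 13.3 and interferon-stimulated genes 10 of 25 (IFITM2 4.14, IFIH1 3.83) at 31.04. HOX genes had 13 of 39 (HOXA11 5.92, HOXA9 4.98) at 22.6 and ZNF zinc finger genes 226 of 509 (ZNF706 7.31, ZNF367 6.99) at 1.01. Macrophage markers had 4 of 22 (MARCO 2.88, CD68 2.503) at 0.325, and at 0.4 against unmatched random lists. They had 10 of 22 at 34.3 with a window of 2.5 kb and 8 of 22 at 5.43 with any peak over the gene. With peaks at a −log10 q of at least 10 they had 0 of 22 at 0.27. At 0 marked genes neither the macrophage nor the monocyte list could pass the limit in that setting. MHC class II presentation had 1 of 12, the regulator CIITA at 3.80, at 0.46. B cell markers had 2 of 18 (CD79A 5.69, EBF1 2.26) at 0.185 and erythroid markers 2 of 20 (TFRC 4.72, KLF1 4.02) at 0.215. The former lay below random lists with any peak over the gene counted (0.08), and the latter below unmatched random lists (0.05).

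**Figure D2:**
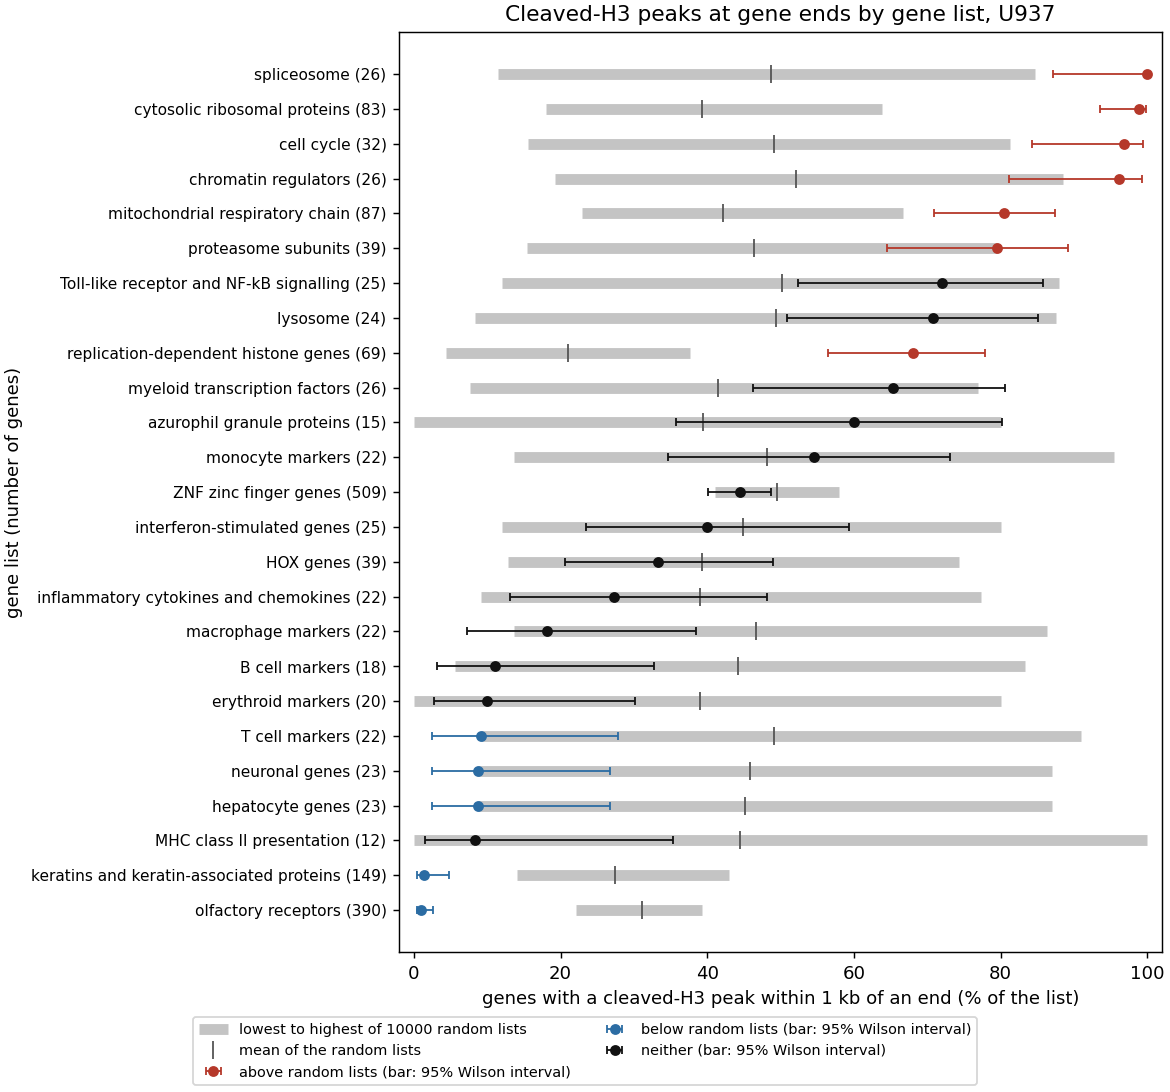
Genes with an H3ΔN peak within 1 kb of an end, as a share of each of the 25 lists (%, horizontal axis; the number of genes is given beside each name). Points are the observed shares with 95% Wilson intervals, red for the 7 lists above, blue for the 5 below and black for the 13 inside the limits set by 10000 random lists, whose mean and full range are drawn in grey. Ribosomal protein, cell cycle and spliceosome genes sit near 100%, and olfactory receptors at 1.03%.

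Among genes named in advance for the cells and the enzymes, those of the 3 proteases carried H3ΔN at an end, as did 45.7% of all protein-coding genes. The CTSG gene had a peak of fold 3.65 at chromosome 14, 24576522 to 24577371. The PRTN3 gene had one of 3.31 and the ELANE gene one of 2.67, both in the cluster on chromosome 19 that also holds AZU1 (6.91). The strongest region of that cluster, with a fold of 9.06 at 823468 to 824531, lay nearest to PLPPR3. SPI1, the master regulator of myeloid cells, had 4.12 at an end, CSF1R, the receptor for M-CSF, 3.28 and MYC 5.50. CD14, the co-receptor for lipopolysaccharide, had no H3ΔN peak at an end, and the nearest lay 5809 bp away.

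The next comparison asked whether regions of the protease lists overlap H3ΔN regions. Regions recovered with the PRTN3 antibody overlapped H3ΔN regions more often than random placements did. Of 51 PRTN3 regions on chromosomes 1 to 22 and X, 27 (52.9%, interval 39.5 to 65.9%) overlapped an H3ΔN region, against a mean of 0.605 regions and a highest value of 4 in 1000 placements, a ratio of 44.6. With placements that kept each region's position class the mean was 4.06 regions and the ratio 6.66. Of the 27 overlapping regions 18 lay within 1 kb of a histone gene, and the other 9 included 2 loci that all 5 lists recovered. The interval and the placements treat regions as independent, but 19 of the 51 sat on chromosome 6 in the histone gene clusters. The overlap thus rests largely on histone genes. Of 224 CTSG regions 3 (1.34%) overlapped H3ΔN, and 342 of the 1000 placements reached that number. For ELANE the overlap was 3 of 6 regions, above all placements, and for bulk H3, run the same way as an antibody control, 2 of 12, which 12 placements reached. Without regions shared with another list apart from H3ΔN, ELANE had 1 of 4, which 30 placements reached, and CTSG 1 of 222. Summits of the PRTN3 list also lay at gene ends: 36 of 62 (58.1%, interval 45.7 to 69.5%) against a mean of 2.80% in the placements. No CTSG summit of 224 lay at a gene end, which allows a share of up to 1.34%, and 10 of 1000 placements had none either.

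Regions of the PRTN3 list lay at histone genes. Of 69 replication-dependent histone genes, whose transcripts carry a stem-loop in place of a poly(A) tail, 25 had a PRTN3 region within 1 kb of an end (36.2%, interval 25.9 to 48.0%). The mean of 10000 random lists was 1.36 genes and the highest 7, and this was the only one of the 25 lists to stand apart for PRTN3. The strongest lay on H1-4 and within 1 kb of H2BC5, with a fold of 8.13 at chromosome 6, 26156396 to 26157336, where the H3ΔN region had a fold of 8.45. H1-2 followed at 6.58, H2AC12 at 6.53, in a region also within 1 kb of H2BC12, and H2BC21 at 6.25. Regions on H2BC5 and H2BC12 themselves had folds of 4.46 and 5.41. All histone classes were represented, with 3 of 6 H1, 8 of 17 H2A, 7 of 18 H2B, 3 of 13 H3 and 4 of 15 H4 genes. Of the 25 genes 23 also carried H3ΔN, and 20 of the 69 had neither. Only 7 other protein-coding genes had a PRTN3 region at an end: WDR74, TAF12, ZFP36L2, TSPOAP1, EIF3G, RPL36 and LONP1. Among the 83 ribosomal protein genes RPL36 was the only one. On the assembled chromosomes, 0 of 224 CTSG, 0 of 6 ELANE and 0 of 12 bulk H3 regions lay within 1 kb of a histone gene. These counts allow shares of up to 1.34%, 50% and 25%. The PRTN3 share of 41.2% lay above the limits for CTSG and bulk H3, but not above that for ELANE. The upper Wilson bound for 0 of 6 was 39.0%, below that share, so the contrast with ELANE turns on the limit used. Random placements of the CTSG, ELANE and bulk H3 lists had means of 0.016, 0 and 0 regions, so a count of 0 does not set them apart from random placement.

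**Figure D3:**
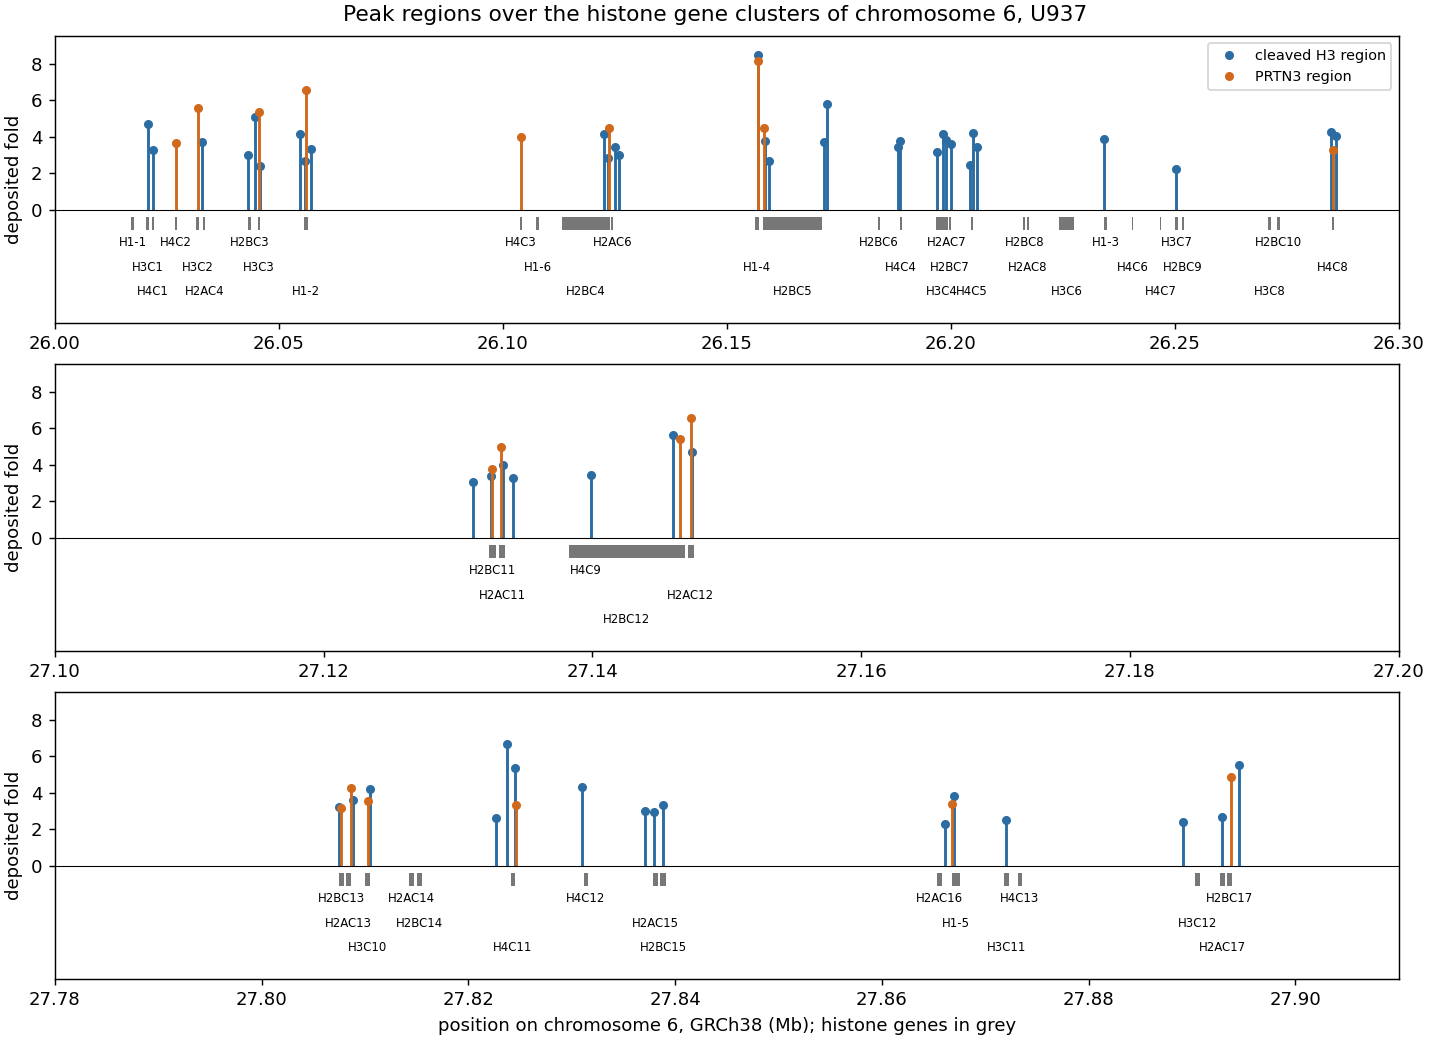
Peak regions over 3 stretches of the histone gene clusters on chromosome 6 (horizontal axis, Mb on GRCh38), drawn at the region's middle with the deposited fold as height (vertical axis). Blue marks are H3ΔN regions, orange marks PRTN3 regions and grey boxes histone genes. PRTN3 and H3ΔN meet at H1-4, with folds of 8.13 and 8.45, while H4C2 and H4C3 carry PRTN3 at 3.64 and 3.98 without an H3ΔN region.

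The last comparison asked which regions the lists have in common. A small set of places appeared in nearly every list. At 7 loci, 3 or more of the 5 lists had a region, and 5 of these loci were in all 5 lists. The loci in all lists on assembled chromosomes were chromosome 15, 19777289 to 19779959, and chromosome 3, 93470379 to 93470780. The other 5 of the 7 lay on unplaced scaffolds. At the chromosome 3 locus the fold was at most 4.11 in any list, while −log10 q ran from 918 for H3ΔN to 3404 for ELANE. Signal that all 5 antibodies share, bulk H3 included, describes the region and not a single antibody. The 7 loci held 50.0% of the ELANE regions (7 of 14), 36.8% of the bulk H3 regions (7 of 19), 10.5% of the PRTN3 regions, 2.62% of the CTSG regions and 0.0192% of the H3ΔN regions. Off the chromosomes 1 to 22 and X lay 8 ELANE, 7 bulk H3, 6 PRTN3, 5 CTSG and 10 H3ΔN regions. The strongest CTSG regions away from these loci were at chromosome 7, 82633987 to 82634220 (4.54), 119792 bp from PCLO, and inside CNTN4 on chromosome 3 (4.52). The strongest bulk H3 regions away from them had folds of 4.81 on chromosome 1, nearest to H3-7 at 650329 bp, and 4.46 on chromosome 13, nearest to PCDH20 at 396075 bp.

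Over the autosomes, H3ΔN regions were densest on chromosome 19, with 26.3 per Mb, and sparsest on chromosome 4, with 5.69. CTSG regions followed another order: chromosome 13 held 32 of the 224, where its length would give 7.98, and chromosome 2 held 35 against 19.8. Chromosome 8 had 23 against 11.7, chromosome 21 had 9 against 3.34, and chromosomes 16 and 22 had none against 6.66 and 3.27.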

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

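All tests in this part were chosen after the result was seen. The ELANE list held 1 region on the Epstein-Barr virus contig that accompanies the human assembly, from position 7434 to 9147, with a deposited fold of 1395 and a −log10 q of 20147. The next highest fold of that list was 11.9. The region is counted in the list sizes above and stood out as signal in viral sequence, which the comparisons with genes and H3ΔN do not use. It had 3 summits over 1714 bp. A single DNA segment in this library, such as a carried-over piece of DNA, is a candidate explanation, but the 0 other regions of the ELANE list on the contig only restate what was seen and decide nothing. This part of the viral genome holds its latent origin of replication, which is also built into some plasmids. For a viral genome carried by the cells, 0 of the other 4 lists had a region on the contig, but a list called against a control would hide an evenly present virus, and the control is not known. Both explanations stay open, and no biological explanation was tested.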

How the results depend on the processing

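No paired analysis was possible because each antibody has 1 library with a file, and for the same reason no library could be left out. Of 193 alternative values 156 kept their direction and side of the limit or, for counts, stayed within 1.5 times. Settings chosen after the data were seen were q at most 0.05, summit entries for overlaps, placements over whole chromosomes and the 3 alternatives for PRTN3 at histone or snRNA genes. Counts of peak entries moved with the threshold: at a −log10 q of at least 5 they were 16804 for H3ΔN, 10 for bulk H3, 7 for CTSG, 37 for PRTN3 and 11 for ELANE, at 10 they were 7159, 10, 7, 18 and 11, and CTSG had 63 at a q of at most 0.05. On chromosomes 1 to 22 and X alone bulk H3 had 14 entries and ELANE 6. Off these chromosomes, regions at a −log10 q of at least 10 numbered 4 for H3ΔN, 3 for CTSG and 5 for ELANE. The excess of H3ΔN at gene ends kept its direction under all alternatives run, from 6.59 times the placements with a window of 2.5 kb to 20.8 times at a −log10 q of at least 10, while the ratio inside protein-coding genes turned to 1.06 with a window of 500 bp, since fewer summits then count as gene ends. The overlap of PRTN3 with H3ΔN ranged from 27.5 to 59.7% and stayed above all placements. Overlaps of short lists rested on few regions: at a −log10 q of at least 5 the share was 100% for CTSG, bulk H3 and ELANE (2 of 2 each, the loci on chromosomes 15 and 3 that all 5 lists share), without regions of other lists it was 0 for bulk H3, 0.45% for CTSG and 25% for ELANE, and ELANE had 33.3% with H3ΔN peaks at a −log10 q of at least 10. The shares without regions of other lists fell because these loci were left out. Lists below random lists fell from 5 to 2 at that threshold and ranged up to 6 with unmatched lists, and lists above ranged from 6 to 8. Part of that fall was fixed in advance, since the T cell and hepatocyte lists had 0 marked genes there and still could not pass the limit. Of 100 list percentiles under alternatives, 87 kept their side, 7 fell back inside the limits, 5 went past them and 1, that of monocyte markers at a −log10 q of at least 10, moved from 71.7 to 0.335. The gain in gene-end share from the lowest to the highest quartile ranged from 24.3 to 42.2 percentage points. Placements matched on base composition, random lists matched on CpG content and the base composition of peaks were not run, since no genome sequence was used here. Depth is unknown, so short lists cannot be told from shallow libraries or from evenly spread signal.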

Other observations

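In this part the histone list was fixed in advance, while the snRNA class, its union with the histone list, the domains and the tests of explanations were chosen after the results were seen. Regions of the PRTN3 list also lay on genes of small nuclear RNAs, the RNA parts of the splicing machinery. Of its 51 regions on chromosomes 1 to 22 and X, 21 lay within 1 kb of a histone gene and 10 within 1 kb of an snRNA gene, together 60.8% (interval 47.1 to 73.0%) against a mean of 0.037 regions and a highest value of 2 in 1000 placements. The strongest PRTN3 region of all, with a fold of 8.66, covered RNU5F-1 (chromosome 1, 44721591 to 44721901). RNU2-2 followed at 8.62, RNU11 of the minor spliceosome at 6.82 and RNU5A-1 at 6.32, and the RNU2-2 and RNU11 regions are those counted at WDR74 and TAF12. For cleaved H3, 18 of the 21 regions near histone genes overlapped an H3ΔN region (85.7%, interval 65.4 to 95.02%), and 0 of the 10 near snRNA genes did, which allows up to 30%. Within 1 kb of the gene, 4 of the 10 snRNA genes with PRTN3 and 23 of the 25 histone genes with PRTN3 had an H3ΔN region, and the difference between the classes was not tested. Of the 20 PRTN3 regions near neither class 9 overlapped H3ΔN, among them MYC (PRTN3 4.77, H3ΔN 5.50), MIR142HG and MIR223HG, hosts of microRNAs of blood cells, and ZFP36L2, while 2 of the 9 were the loci on chromosomes 15 and 3 that all 5 lists share.

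H3ΔN formed wide domains at some loci. When regions less than 12.5 kb apart were joined, the domain with most covered sequence lay in the HOXA cluster (chromosome 7, 27137406 to 27202580), with 31 regions and 30.3 kb covered, over part of HOXA3 and on to HOXA13, with HOXA4 outside it. BMI1 with COMMD3 came next with 22 regions and 21.7 kb, and CEBPA (21 regions), GFI1 (8), MYB (13) and RUNX1 (10) were among the first 20 of 15674 domains, as were RNF220 (20), DENND3 (26), GRK2 (12) and RAB27A (17). Long genes rarely had H3ΔN at both ends. Of 14315 protein-coding genes over 10 kb, 7189 had it at neither end, 6802 at 1 end (47.5%) and 324 at both, where 968 would be expected if the ends were independent (890 to 1033 in permutations). Among other gene types, 22.8% of tRNA genes, 15.9% of long noncoding RNA genes, 10.4% of snRNA genes and 2.12% of pseudogenes had an H3ΔN region at an end.

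The placement of PRTN3 on histone and snRNA genes was weighed against technical explanations. As a test of regions recovered by any antibody, 0 of the 31 PRTN3 regions overlapped any of the 242 bulk H3, CTSG and ELANE regions, but these lists are short and of unknown depth and were already seen to hold no region near such genes, so recovery by any antibody stays open. As a test of strong H3ΔN signal, 3 of the 100 genes with the highest H3ΔN fold at an end (H1-4, H2BC5 and ZFP36L2, with all folds at least 7.66) had a PRTN3 region. Only 32 protein-coding genes had one at all, in a list of unknown depth, so at most 32 of the 100 could have one. The count shows only that most genes with a PRTN3 region lay outside the 100 strongest. The share is above the 0.16% of all protein-coding genes, and H3ΔN regions under PRTN3 had a median fold of 4.23 against 3.05 elsewhere. A relation to strong H3ΔN signal therefore stays open. Binding of the PRTN3 antibody to another protein at these genes stays open, since there is 1 antibody and no sample without the protease. That PRTN3 itself sits at these genes is a hypothesis.

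The uneven spread of CTSG regions over the autosomes was weighed in the same way. It rests mostly on weak calls, since 61 of all 229 CTSG regions passed a q-value of 0.05. As a test of spread by chromosome length, 0 of 10000 draws gave a chi-square distance as large as the observed 168 (highest 61.7), which argues against length alone. The copy number of the chromosomes in U937 may contribute: CTSG regions per Mb fell as the 10th percentile of H3ΔN fold rose, taken as a stand-in for background because peaks pass at a lower fold where reads are denser, with Spearman's rho of −0.644 (permutation p = 0.00168, adjusted 0.00759) and Pearson's r of −0.604 (permutation p = 0.00253, adjusted 0.00759) over 22 autosomes, and without chromosomes 20 and 15 r was −0.667 and rho −0.608 (permutation p = 0.00499). Low gene density may contribute too: rho was −0.54 (permutation p = 0.0101, adjusted 0.0203), r −0.393 (permutation p = 0.0671, adjusted 0.0752) and without chromosomes 19 and 17 r was −0.443 (permutation p = 0.0486) and rho −0.426 (permutation p = 0.062), and with ranks adjusted for the 10th percentile rho was −0.782 (permutation p = 1e-05, the smallest possible). Both stay open, 6 p-values of 3 relations were adjusted together, chromosomes of 1 library are not replicates, and no biological explanation was tested.

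On chromosome 13 the lowest of the 32 CTSG regions started at 46.8 Mb. From there on 681 H3ΔN regions had a 10th percentile of fold of 2.25, against 2.35 for the 280 regions before. The boundary was set by the CTSG regions themselves, and the difference was not tested. For the third relation, H3ΔN regions per protein-coding gene against the 10th percentile of fold, rho was −0.418 (permutation p = 0.0541, adjusted 0.0752) and r −0.387 (permutation p = 0.0752, adjusted 0.0752), and without chromosomes 20 and 15 r was −0.329 and rho −0.293.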
